A study of Homo sapiens with 30 samples.

How the data were processed

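Chromatin contacts of the NOTCH1 promoter and of the CTCF sites S2 and S4 were profiled by 4C-seq in K562 cells. For each viewpoint there were 2 libraries of unedited (WT) cells and of cells mutated at S2, S4, S5 or both S4 and S5. Per the labels' protocols, 10 M cells were fixed for 10 min in 2% formaldehyde, chromatin was digested with DpnII in 3 rounds and ligated, the DNA was cut with NlaIII or CviQI and ligated again, and 200 ng of template was amplified by 16 cycles of a first PCR before a second. Which second enzyme served which viewpoint is not stated. Libraries were sequenced as single reads of 150 bp on an Illumina instrument. 4C reads carry no molecular identifier, so reads at 1 fragment end are not independent ligation events.

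Each deposited table lists the restriction fragment ends of chromosome 9 for 1 library, marked blind or non-blind, with 382657 ends at the promoter, 429740 at S2 and 428705 at S4. Per the file headers, each holds whole read counts per fragment end, which the authors deposited without normalization. A second deposited column holds a signal that equals the count, times a constant, divided by the chromosome 9 total without the 2 most covered ends. A further deposited column holds a signal that equals the centred mean of that column over 21 ends. Both relations were found from the values. The submitters' processing notes name deepTools and hg19, with no role or version, and the aligner, the read filters and the counter are not given in the sources used here. Only the counts were used, since smoothed or scaled signal is unsuited to a count model. The tables cover chromosome 9, so signal on other chromosomes and scaling to a genome-wide total, both planned, are not analysed here, and the planned share of signal on chromosome 9 was replaced by the near-cis share of chromosome 9 reads.

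The viewpoint was placed at the centre of the 5-kb window with the highest sum over its 10 libraries. Reads within 5 kb of it were masked, because undigested and self-ligated fragments dominate there, and reads within 500 kb outside the mask were called near-cis. Near-cis ends were summed in 10-kb bins on a fixed grid. Bins with a mean under 10 reads per library were left out, which kept 96 bins at the promoter, 95 at S2 and 97 at S4. Library sizes were the near-cis totals, which ran from 64583 to 2691302 reads, of 1437870 to 8008761 on chromosome 9. What the 2 replicates of a genotype share, such as a culture, a ligated template or a PCR, is not given in the sources used here, and the spread between them sets every p-value. Amplification without identifiers, few captured ligation events and the share of random ligation can each move such shares, and a share can fall in 1 region because another rises.

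Bins were tested with edgeR's quasi-likelihood F test, with all 10 libraries of a viewpoint in 1 fit, for each mutant against WT, for the S4-S5 mutant against each single mutant, for the S4 by S5 interaction and for any difference among genotypes. Tests were two-sided, p-values were Benjamini-Hochberg adjusted over the bins of a contrast, and 0.05 was the threshold. The bins named were fixed by a rule before the data were examined. They are, for each mutant and viewpoint, the 3 with the largest log2 fold change in each direction among bins past the threshold whose mutant libraries both lie beyond both WT libraries, the bins holding the other viewpoints, and the 3 bins with the highest WT mean outside 50 kb. The report gives those at the other viewpoints in full and the most changed ones in part. A mutant with 0 reads in a bin was given a lower bound on its fold with a floor of 3 reads over both libraries. Bounds and intervals from counts cover counting error only.

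Values per library were the near-cis share, the share within 50 kb, the log2 ratio of the telomeric to the centromeric side, the share within 10 kb of each other viewpoint (20 kb in all), the share between the outermost viewpoints and the slope of log reads against log distance. Genotypes were compared by an exact permutation of the between-genotype F statistic over every parting of 10 libraries into 5 pairs, adjusted over a family of 42 values, 21 of them added after the data were examined. Shares of larger regions were added at that point, as were their log2 folds with 95% intervals from 2000 resamplings of fragment ends. The far centromeric region and the 100 kb telomeric of S4 were singled out after their values were seen, and folds of 4 other intervals, nearer to the viewpoints, are not reported. The mutant reference, also added, replaces WT by mutants that keep the site in question: the S4, S5 and S4-S5 mutants for S2, the S2 and S5 mutants for S4, the S2 and S4 mutants for S5 and the S2 mutant for the S4-S5 mutant.

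Alternatives fixed before the data were examined were scaling to the chromosome 9 total, TMM factors, DESeq2 with its size factors, bins of 5 or 20 kb, a mask of 20 kb, windows of 250 kb and 1 Mb, contact windows of 5 or 20 kb on each side, no count minimum or one of 40, fragment ends capped at the 99th percentile of the covered ends of their library, covered ends in place of reads, only the 4 libraries compared, the replicate number as a block, adjustment over the 4 mutants together, and each library left out in turn. The mutant reference, summed replicates with additive mutation effects, a fit without the S2 mutant, non-blind ends, removal of ends under 1% of the highest library, a 2-fold minimum and chromosome 9 scaling of the region folds were added later. Pseudocounts do not apply to counts. The far regions end at the window's edge, so within 250 kb only their part nearest the viewpoint is left, and within 1 Mb they reach farther. Within 250 kb little remains of the far centromeric region seen from S4 and of the far telomeric region seen from S2. Folds of far regions in these windows thus describe other stretches than the reported ones. The planned counts per neighbouring gene need an hg19 annotation, which was not used here. RefSeq's GRCh38 table served only for gene names and their order.

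The bin test was tested on simulated counts drawn with the mean share of each bin over the 10 libraries, their near-cis totals and the fitted dispersion, with changes put into the S4 mutant. Against WT, it recovered 10 of 10 bins changed 1.5-fold and 10 of 10 changed 2-fold at each viewpoint, 10, 9 and 10 of 10 changed 1.25-fold, and called 0 of 66, 0 of 65 and 0 of 67 unchanged bins. The dispersion is that between the deposited replicates of a genotype, so the simulation tests the method at that spread only. The exact test gave p under 0.05 in 15 of 200 simulated sets without an effect and in 50 of 50 with one. The simulated effect was many times the simulated SD, so power at smaller effects was not tested. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.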

Results

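The series holds 30 4C-seq libraries from K562, a human chronic myeloid leukaemia cell line. 4C-seq ligates cross-linked, digested chromatin and counts, for 1 chosen restriction fragment (the viewpoint), the fragments it was joined to, so that a read count at a fragment end reflects how often that place contacted the viewpoint. The 3 viewpoints lay on chromosome 9 around NOTCH1, which encodes a receptor of the Notch signalling pathway. They were the NOTCH1 promoter and CTCF sites named S2 and S4. CTCF is a DNA-binding protein found at many loop anchors and domain boundaries. Each viewpoint was profiled in unedited (WT) cells, in cells mutated at S2, S4 or S5, and in cells mutated at both S4 and S5, with 2 libraries for each of the 15 groups. The comparisons ask whether mutation of a CTCF site changed what the promoter, S2 and S4 contacted.

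In hg19 coordinates, the most covered 5-kb window of the promoter libraries was chromosome 9, 139440768 to 139445767. That of the S2 libraries was 139383372 to 139388371, 57.4 kb centromeric of the promoter, and that of the S4 libraries was 139521246 to 139526245, 80.5 kb telomeric of it. S2 and S4 thus lay 137.9 kb apart with the promoter between them. In RefSeq's GRCh38 order of protein-coding genes, SEC16A, INPP5E and PMPCA are the next ones centromeric of NOTCH1, and EGFL7, AGPAT2 and DIPK1B are the next telomeric ones. The position of S5 is not given in the labels, and exons, introns and UTRs were not assigned because no hg19 annotation was used here.

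Libraries held 1437870 to 8008761 chromosome 9 reads. WT libraries were the shallowest in total, with 1437870 to 2326487 reads against 3500663 to 8008761 in the mutants. Near-cis reads, those within 500 kb of the viewpoint but outside 5 kb, numbered 64583 to 2691302 per library. The lowest values were in the S2 mutant at the promoter viewpoint, where a single fragment end took 98.3% ± 0.0114 of all reads (SD, n = 2).

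WT libraries stood apart from every mutant. At the promoter viewpoint 66.7% ± 0.0523 of WT reads outside the mask were near-cis (SD, n = 2), against 82.6 to 85.7% in the 8 mutant libraries. The WT share was 70.0% ± 0.00238 against 81.6 to 88.2% at S2, and 73.4% ± 0.0993 against 88.0 to 89.9% at S4. WT libraries also had reads at more near-cis fragment ends, 54.1 to 55.2% against 33.7 to 52.6% at the promoter, 57.2 to 57.7% against 39.0 to 48.0% at S2 and 57.5 to 57.6% against 41.0 to 48.3% at S4. The mask around the viewpoint held 77.3 to 77.8% of WT chromosome 9 reads at the promoter, against 88.1 to 98.6% in the mutants. It held 59.8 to 60.3% against 61.3 to 76.7% at S2, and 31.4 to 32.1% against 56.8 to 90.9% at S4. How this bears on the contrasts with WT was not tested. The near-cis share differed among genotypes in an exact permutation test at each viewpoint (upper-tail exact p = 0.00212, 0.00106 and 0.00317, Benjamini-Hochberg adjusted 0.00269, 0.00165 and 0.00351 over 42 values).

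**Figure D1:**
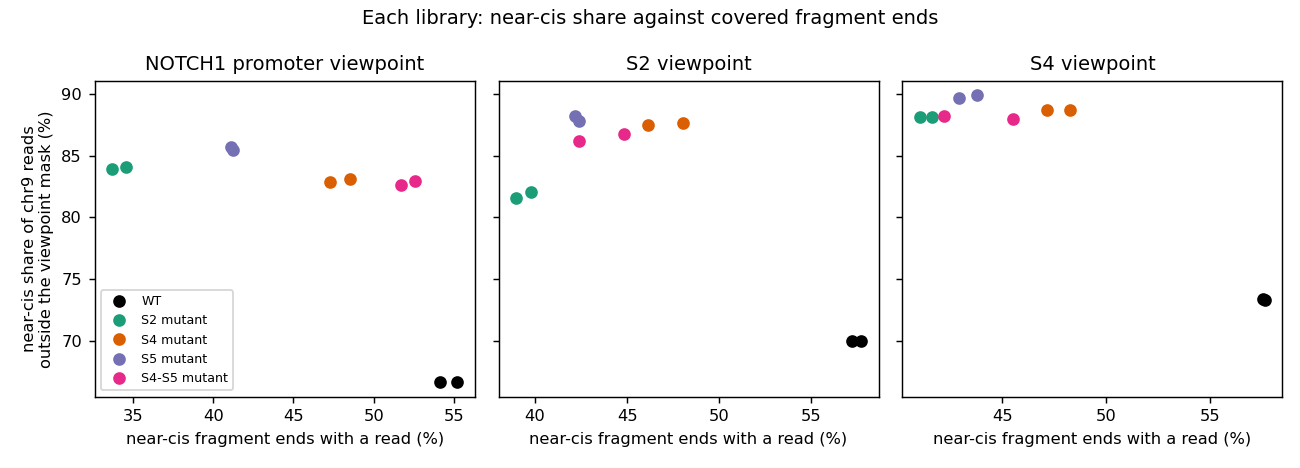
Each point is 1 library; the horizontal axis gives the percent of near-cis fragment ends with a read and the vertical axis the percent of chromosome 9 reads outside the viewpoint mask that were near-cis. WT libraries (black) lie at 66.7 to 73.4% near-cis, below all mutant libraries, which lie at 81.6 to 89.9%.

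The 2 libraries of a genotype were close to identical at single fragment ends, and different genotypes were not. Over near-cis ends, log2 reads correlated at r = 0.945 to 0.99 within genotypes and 0.212 to 0.555 between them (across fragment ends, which are not independent replicates). The replicate counts differed by more than counting error, with a chi-square of 1.29 to 32.6 per degree of freedom, which separate amplifications of 1 template would also give, so this does not show 2 independent samples. They were treated as 2 samples as the labels list them. Nothing in the labels says that they came from separate cultures, so p-values below measure the spread between these libraries, which may be technical. Region folds are given with 95% intervals from resampling fragment ends, a choice made after the data were examined. These intervals resample ends of the mean profile of 2 libraries. Variation between cultures, templates and lines is therefore not in them, and an interval that excludes 0 does not show a reproducible genotype effect.

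In WT cells S2 and S4 contacted each other more than either contacted the nearer promoter bin. From S4, the 10-kb bin holding S2 (139380001 to 139390000) took 5.88% ± 0.134 of near-cis reads (SD, n = 2), the highest value outside 50 kb, while the bin holding the promoter took 2.32% ± 0.131. From S2, the bin holding S4 (139520001 to 139530000) took 5.30% ± 0.0224, again the highest outside 50 kb, and the promoter bin 1.95% ± 0.000379. Outside 50 kb, the promoter itself contacted the centromeric flank of S4 most, with 4.28% ± 0.0361 in the bin from 139510001, 3.72% ± 0.0106 from 139500001 and 3.38% ± 0.0200 from 139490001. Its bins holding S2 and S4 took 3.24% ± 0.0321 and 1.90% ± 0.0341. No test was run between bins of 1 profile, since bins differ in fragment ends.

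**Figure D2:**
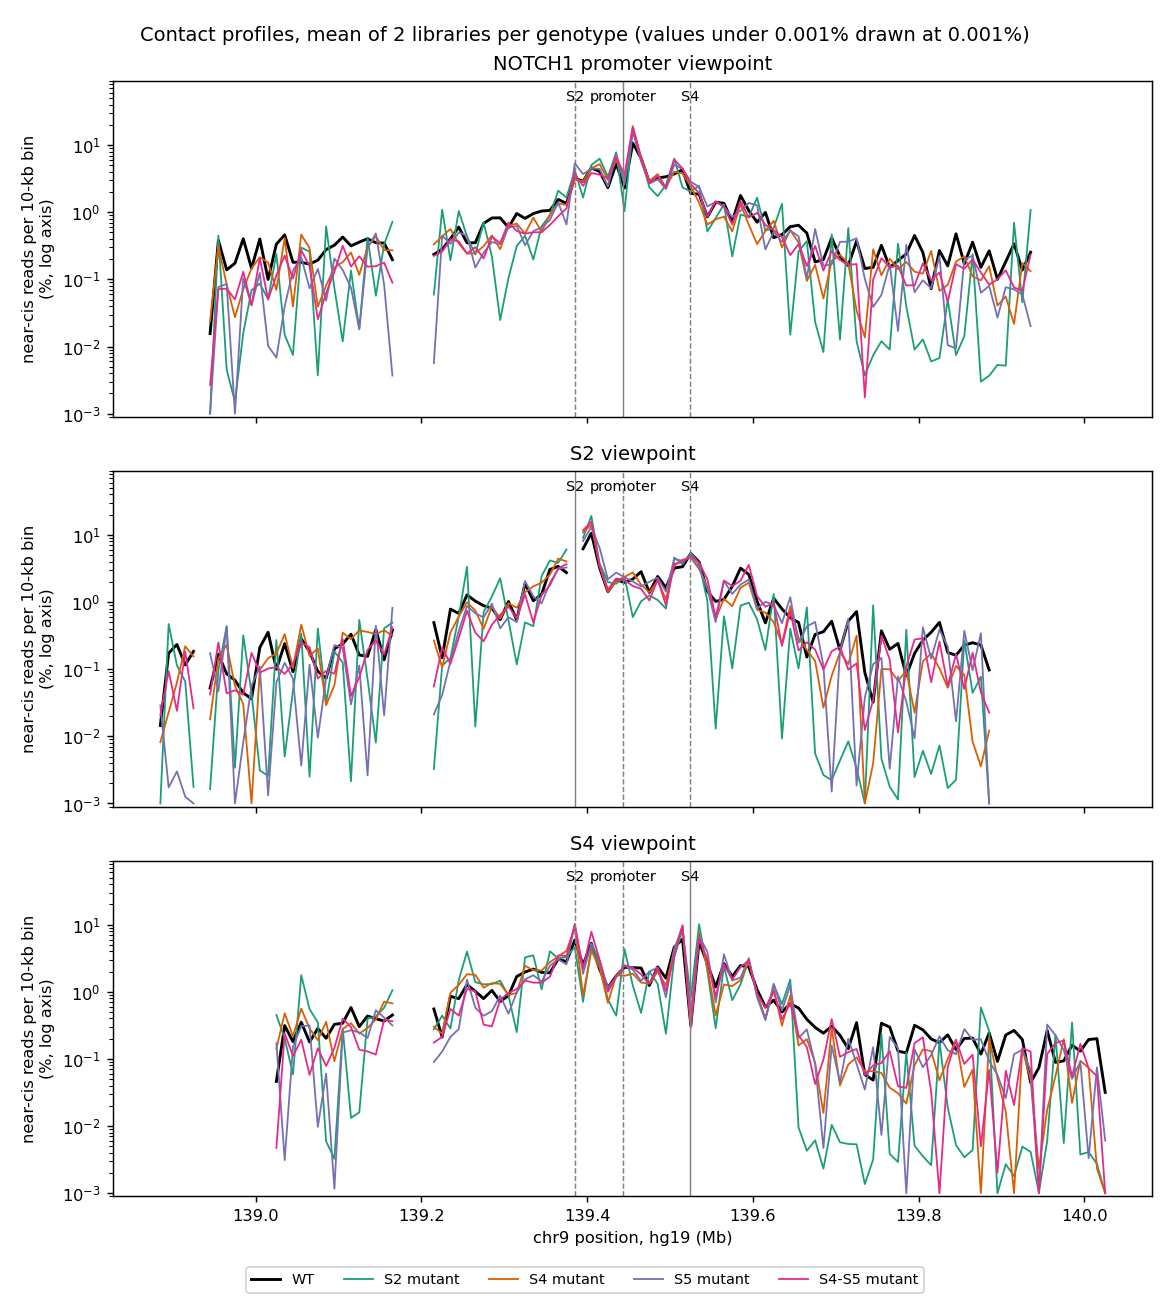
Percent of near-cis reads per 10-kb bin (log axis) against hg19 position on chromosome 9 (Mb) at the 3 viewpoints; lines are means of 2 libraries per genotype, gaps are bins left out of the test, and vertical lines mark the viewpoints. The WT line reaches 5.88% at S2 from S4 and 5.30% at S4 from S2.

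At the promoter viewpoint, both lines with a mutated S5 site had fewer contacts with the far centromeric region, more than 100 kb beyond S2 (138947458 to 139285528). Its share was 9.43% ± 0.000856 in WT, 4.61% ± 0.0388 in the S5 mutant and 5.20% ± 0.0186 in the S4-S5 mutant (SD, n = 2), log2 folds of -1.03 (95% interval -1.48 to -0.63) and -0.86 (-1.12 to -0.60). The S4 mutant, at 7.06% ± 0.0906, had a smaller fold of -0.42 (-0.72 to -0.11), whose sign turned against a mutant reference (0.23) and whose interval reached 0 when scaled to chromosome 9 (-0.10), with a 20-kb mask (-0.21) and within 250 kb (-0.34). Within 250 kb the S5 mutant's fold was -0.62, and against a mutant reference the S4-S5 mutant's was -0.59, both with intervals that included 0. The 250-kb window keeps only the part of the region nearest the promoter. The S2 mutant had 7.82% ± 0.0159 and a fold of -0.27 (-0.97 to 0.25), or -0.38 with an interval below 0 in covered ends. The S5 and S4-S5 mutants had -0.35 and -0.13 in covered ends, so there the fall was not particular to the S5-mutated lines. Covered ends were not matched for depth, however, and the S2 mutant's libraries were the shallowest (64583 and 68827 near-cis reads). Its fall in covered ends was not separated from that. The S4 mutant also had fewer contacts in the 100 kb telomeric of S4, 8.07% ± 0.0476 against 11.5% ± 0.0569 (log2 -0.51, -0.78 to -0.25; -0.19 when scaled to chromosome 9 and -0.00 in covered ends, intervals including 0). In that region the S5 and S4-S5 mutants, at 12.2% ± 0.0124 and 11.3% ± 0.0108, had intervals that included 0 (0.09 and -0.03). Scaled to chromosome 9 they had 0.45 and 0.28, and the S5 mutant had 0.11 in covered ends and 0.40 (0.10 to 0.74) against the mutant reference, all with intervals above 0.

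Contacts of the promoter with the bin holding S2 rose in the S5 mutant, to 5.38% ± 0.0306 (log2 0.73, SE 0.02, edgeR adjusted p = 2.54e-90), the S2 mutant (4.20% ± 0.0875, 0.38) and the S4-S5 mutant (3.79% ± 0.0137, 0.23, which turned to -0.15 against the mutant reference). The S4 mutant's small decrease there (-0.08) turned to an increase under other scalings. Over 20 kb around S2 the rise in the S5 mutant had a bootstrap log2 fold of 0.56 (0.07 to 0.98), whose interval included 0 within 250 kb (0.46) and over 10 or 40 kb around S2 (0.68 and 0.28), and the S2, S4 and S4-S5 mutants had 0.03, -0.03 and 0.03 with intervals including 0. The bin holding S4 rose in all 4 mutants, by log2 0.11 in the S2 mutant (-0.36 against the mutant reference), 0.35 in the S4 mutant (0.00 against it), 0.59 in the S5 mutant and 0.47 in the S4-S5 mutant. Over 20 kb around S4, however, the S2 mutant had a lower share than WT (4.04% ± 0.172 against 4.71% ± 0.0118), and the intervals of the S2, S4 and S5 mutants included 0 (-0.22, -1.21 to 0.60; 0.10, -0.27 to 0.51; 0.29, -0.24 to 0.81). The S4-S5 mutant had 0.36 (0.05 to 0.71), whose interval included 0 within 250 kb (0.26), on covered or non-blind ends (0.08 and 0.30), over 10 kb (0.32) and against the mutant reference (0.58). Among the bins on the centromeric flank of S4, that from 139500001 rose by log2 0.71 to 6.07% ± 0.0312 in the S4-S5 mutant (-0.05 against the mutant reference), by 0.76 in the S2 mutant, 0.46 in the S5 mutant and 0.11 in the S4 mutant (-0.50 against the mutant reference). That from 139510001, the highest of them in WT, fell to 2.34% ± 0.161 in the S2 mutant (log2 -0.87; 0.21 with DESeq2) and to 3.78% ± 0.0723 in the S4 mutant (-0.18, which turned to 0.14 to 0.44 under the other 3 scalings). It was 0.04 in the S5 mutant, which turned to -0.06 within 250 kb, and 0.07 in the S4-S5 mutant. The neighbouring bin from 139490001 fell in all 4 by -0.40 to -0.61 with near-cis scaling and lay between 0.08 and 0.68 with DESeq2's size factors.

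By edgeR's quasi-likelihood test, 91 of 96 bins changed in the S2 mutant at the promoter viewpoint (27 higher, 64 lower), 87 in the S4 mutant (24, 63), 90 in the S5 mutant (25, 65) and 84 in the S4-S5 mutant (15, 69). At least 2-fold changes numbered 54, 29, 42 and 29. The S2 mutant, with the most here and at S2 and S4, also had the lowest mean share of near-cis ends with a read. Its 2-fold changes were not separated from that. The excess of lower bins depended on scaling. Scaled to all of chromosome 9 the higher and lower bins were 33 and 59, 40 and 49, 37 and 50, and 36 and 53, with TMM factors 37 and 52, 38 and 48, 38 and 48, and 37 and 51, and with DESeq2 49 and 41, 52 and 35, 49 and 39, and 46 and 37. When covered ends were counted in place of reads, edgeR called 0 bins in each mutant (8, 0, 1 and 0 at an unadjusted p under 0.05, with no other tool run on them). Whether this test can find changes in so few ends per bin was not simulated. Its 0 calls, here and below, thus do not show that bins were unchanged. The 3 bins that fell most in each mutant lay more than 250 kb from the viewpoint, several of them with few mutant reads. In the S2 mutant the bins from 139930001, 139220001 and 139710001 rose most (log2 2.08, 1.96 and 1.87; the last was -4.14 on non-blind ends), and those from 138970001 and 139880001 fell most, to 2 and 5 reads over both libraries, beside an edge bin from 138940001 with 0 reads. The S4 mutant rose most from 139810001 (1.89) and fell most from 139910001 (-3.97), and the S5 mutant rose most from 139670001 (1.63) and fell most from 138970001 (3 reads over both libraries) beside the same edge bin. In the S4-S5 mutant the bin from 139670001 rose most (0.80), followed by the bin from 139450001 beside the viewpoint, which rose from 10.7% ± 0.0495 to 18.2% ± 0.0411 (0.76; 0.07 and not past the test in covered ends), and that from 139730001 fell most (-6.35). The edge bin with 0 reads in the S2 and S5 mutants was at least 6.92-fold and 18.3-fold lower than in WT, with a floor of 3 reads over both libraries.

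From S2, the far centromeric region (138887502 to 139285528) was again lower in both S5-mutated lines. It held 10.6% ± 0.0325 of near-cis reads in WT, 6.36% ± 0.00585 in the S5 mutant and 5.94% ± 0.0583 in the S4-S5 mutant (SD, n = 2), log2 folds of -0.74 (-1.23 to -0.32) and -0.84 (-1.19 to -0.48). Scaled to chromosome 9 the S5 mutant's fold was -0.41 with an interval that included 0. The S2 mutant (10.0% ± 0.0455) and the S4 mutant (8.95% ± 0.0333) had -0.09 and -0.25 with intervals including 0, but below 0 for the S2 mutant in covered ends (-0.17) and for the S4 mutant within 250 kb or 1 Mb (-0.52 and -0.31). The S5 and S4-S5 mutants had -0.13 and -0.14 in covered ends, smaller falls than the S2 mutant's. Covered ends were not matched for depth, which among the mutants was lowest in the S2 mutant. In the 100 kb telomeric of S4, the S2 mutant fell to 11.2% ± 0.150 and the S4 mutant to 15.03% ± 0.0948 from 19.9% ± 0.00351, log2 -0.82 (-1.78 to -0.12) and -0.40 (-0.70 to -0.13). Scaled to chromosome 9, or on non-blind ends, both intervals included 0, and in covered ends the values were 0.09 and -0.01. The S4 mutant's fold was 0.08 against a mutant reference, and the S2 mutant's was -0.61 with an interval including 0 under a 20-kb mask. In this region the S5 and S4-S5 mutants had -0.13 and 0.10 with intervals including 0, but 0.48 and 0.92 against mutant references with intervals above 0. The S4-S5 mutant's was also above 0 with a 20-kb mask (0.24), scaled to chromosome 9 (0.40), on non-blind ends (0.39) and in covered ends (0.09).

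The contact of S2 with the bin holding S4 moved little. It took 5.40% ± 0.179 in the S2 mutant (log2 0.03, edgeR adjusted p = 0.367), 4.58% ± 0.0399 in the S4 mutant (-0.21), 4.74% ± 0.0506 in the S5 mutant (-0.16) and 4.92% ± 0.0451 in the S4-S5 mutant (-0.11), and the 3 lower values turned to between 0.10 and 0.31 under the other 3 scalings. The promoter bin rose in the 4 mutants by log2 0.29, 0.27, 0.26 and 0.13 (0.07, -0.00, -0.02 and -0.17 against the mutant reference), but over 20 kb around the promoter every bootstrap interval included 0. Bins changed in 88, 82, 88 and 80 of 95 cases in the S2, S4, S5 and S4-S5 mutants, with 27 higher and 61 lower, 26 and 56, 30 and 58, and 27 and 53. At least 2-fold changes numbered 62, 35, 38 and 28. The splits were 31 and 58, 37 and 39, 40 and 46, and 43 and 40 when scaled to chromosome 9. They were 39 and 51, 37 and 40, 41 and 45, and 43 and 40 with TMM, and 44 and 44, 39 and 38, 42 and 44, and 47 and 39 with DESeq2. In covered ends edgeR called 0 bins (0, 1, 0 and 0 unadjusted). The bin from 139740001 rose most in the S2 mutant (log2 4.78, from 0.0322 to 0.890% of reads), that from 139150001 in the S4 mutant (1.46), that from 138960001 in the S5 mutant (2.34) and that from 138990001 in the S4-S5 mutant (2.28). The bins from 139690001 and 139720001 were among the 3 that fell most in both the S2 mutant (-7.83 and -7.75) and the S5 mutant (-8.42 and -8.60).

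From S4, contact with S2 was higher in the S4, S5 and S4-S5 mutants and lower in the S2 mutant. The bin holding S2 rose from 5.88% ± 0.134 to 8.96% ± 0.127, 10.2% ± 0.0417 and 10.1% ± 0.0522 (SD, n = 2), log2 0.61, 0.79 and 0.78 (edgeR adjusted p = 1.06e-13, 3.17e-15 and 4.18e-15). In the S2 mutant it fell to 4.63% ± 0.0860 (log2 -0.35), which turned to 0.23 with TMM factors and 0.52 with DESeq2. In the S4 and S4-S5 mutants the viewpoint itself carries the mutated site, and in the S2 mutant the target does. Seen from S2 these roles are exchanged. The kind of mutation is not given in the labels, so effects on the fragments at these sites were not separated from contact changes. Over 20 kb around S2 the bootstrap fold was 0.64 (0.30 to 0.92) in the S4-S5 mutant, while the intervals of the S2 mutant (-0.30, -1.06 to 0.27), the S4 mutant (0.36, -0.17 to 0.69) and the S5 mutant (0.60, -0.11 to 1.08) included 0. The promoter bin rose in the S2 mutant to 4.32% ± 0.234 (log2 0.89) and fell in the S4 mutant to 1.73% ± 0.00710 (-0.43), which did not pass with capped fragment ends (-0.03). It was 2.44% ± 0.0452 in the S5 mutant (edgeR adjusted p = 0.0895) and 2.48% ± 0.0241 in the S4-S5 mutant (log2 0.09, edgeR adjusted p = 0.0310; -0.80 against the mutant reference). Over 20 kb around the promoter all 4 intervals included 0, with 0.27 (-1.24 to 0.98) in the S2 mutant, -0.38 (-0.88 to 0.03) in the S4 mutant, -0.13 in the S5 mutant and -0.02 in the S4-S5 mutant.

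The far centromeric region seen from S4 (139023825 to 139285528) moved in opposite directions between the lines. Its share rose from 10.7% ± 0.0270 to 15.7% ± 0.103 in the S2 mutant and 13.2% ± 0.0753 in the S4 mutant, log2 0.55 (0.03 to 0.96) and 0.30 (0.05 to 0.54). It fell to 6.70% ± 0.0363 in the S5 mutant and 6.82% ± 0.0317 in the S4-S5 mutant, -0.68 (-1.05 to -0.36) and -0.66 (-0.96 to -0.37). In covered ends the folds of the S2, S4 and S5 mutants were -0.02, 0.02 and -0.06 with intervals including 0. The S2 mutant's fold was -0.06 within 250 kb, and the intervals of the S2 and S4 mutants included 0 within 250 kb, within 1 Mb and on non-blind ends. The 250-kb window keeps only a small part of this region, next to its telomeric end, so it does not test the same stretch. The region 100 kb telomeric of S4 had intervals that included 0 in all 4 mutants, with shares of 18.7% ± 0.0477 to 22.99% ± 0.0904 around 20.6% ± 0.0229 in WT. The S2, S4, S5 and S4-S5 mutants had log2 folds of 0.11, -0.13, 0.16 and 0.05. Other settings gave intervals that excluded 0. Scaled to chromosome 9 the S5 and S4-S5 mutants had 0.45 and 0.31, the S4 mutant had -0.27 against the mutant reference and -0.35 with a 20-kb mask, and the S5 mutant had 0.48 on non-blind ends. In covered ends the S2, S5 and S4-S5 mutants had 0.15, 0.17 and 0.14. Bins changed in 92, 89, 88 and 86 of 97 cases, with 31 higher and 61 lower, 32 and 57, 27 and 61, and 22 and 64, and 58, 29, 30 and 37 by at least 2-fold. The splits were 38 and 56, 42 and 49, 41 and 51, and 38 and 52 when scaled to chromosome 9. They were 44 and 49, 42 and 48, 39 and 52, and 35 and 54 with TMM, and 48 and 44, 42 and 49, 41 and 51, and 38 and 53 with DESeq2. In covered ends edgeR called 0 bins (0 in each mutant unadjusted). The edge bin from 139020001, which the window cuts, rose most in the S2, S4 and S5 mutants (log2 3.30, 1.64 and 1.90; -0.96 and -0.57 against the mutant reference in the S4 and S5 mutants). Counted whole in a 1-Mb window it had 1.39, 0.03 (not past the test) and 0.35. The bin from 139930001 rose most in the S4-S5 mutant (1.52). Inside the window the opposite edge bin, from 140020001, held 1, 3 and 0 reads over both libraries in the S2, S4 and S4-S5 mutants against 596 in WT, the largest falls, but counted whole in a 1-Mb window its log2 folds were 2.00, -1.36 and -0.83.

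Contacts more than 100 kb telomeric of S4 were lower than WT in most comparisons at all 3 viewpoints, but no fold against mutant references had an interval below 0. In the S4 mutant the log2 folds were -0.67 (-0.99 to -0.35), -1.18 (-1.57 to -0.80) and -0.88 (-1.23 to -0.53) from the promoter, S2 and S4, and in the S4-S5 mutant -0.74, -0.76 and -0.69 with intervals below 0. The S2 mutant had -0.61 (-1.63 to 0.04), -1.04 (-2.38 to -0.22) and -0.83 (-1.96 to -0.12), and the S5 mutant -0.57 (-0.94 to -0.21), -0.35 (-0.90 to 0.12) and -0.35 (-0.74 to -0.02). WT libraries also had the lower near-cis shares given above, and scaled to chromosome 9 the folds of the S5 mutant from the promoter and S4 (-0.21 and -0.06) and of the S2 mutant from S2 and S4 (-0.81 and -0.57) had intervals that reached 0. Within 250 kb so did the S4 and S5 mutants from the promoter (-0.43 and -0.23), the S2 and S4-S5 mutants from S2 (-0.37 and -0.54) and the S2 and S5 mutants from S4 (-0.52 and -0.27). That window keeps only the part of the region nearest the viewpoint, and from S2 only a small one. On covered ends the promoter folds of the S4 and S4-S5 mutants were -0.09 and 0.01 with intervals including 0. The S5 mutant's interval from S4 also included 0 with a 20-kb mask, capped ends or non-blind ends (-0.28, -0.26 and -0.35), the S2 mutant's from S4 reached it with that mask or on non-blind ends (-0.71 and -0.83), and the S2 mutant's from S2 did within 1 Mb (-0.49). Against mutant references the folds of the S2, S4, S5 and S4-S5 mutants were 0.05, -0.07, 0.06 and -0.12 from the promoter, -0.27, -0.48, 0.75 and 0.27 from S2, and -0.19, -0.29, 0.50 and 0.14 from S4. Of these only the S5 mutant's from S2 (0.18 to 1.5) and S4 (0.01 to 1.13) had intervals that excluded 0.

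**Figure D3:**
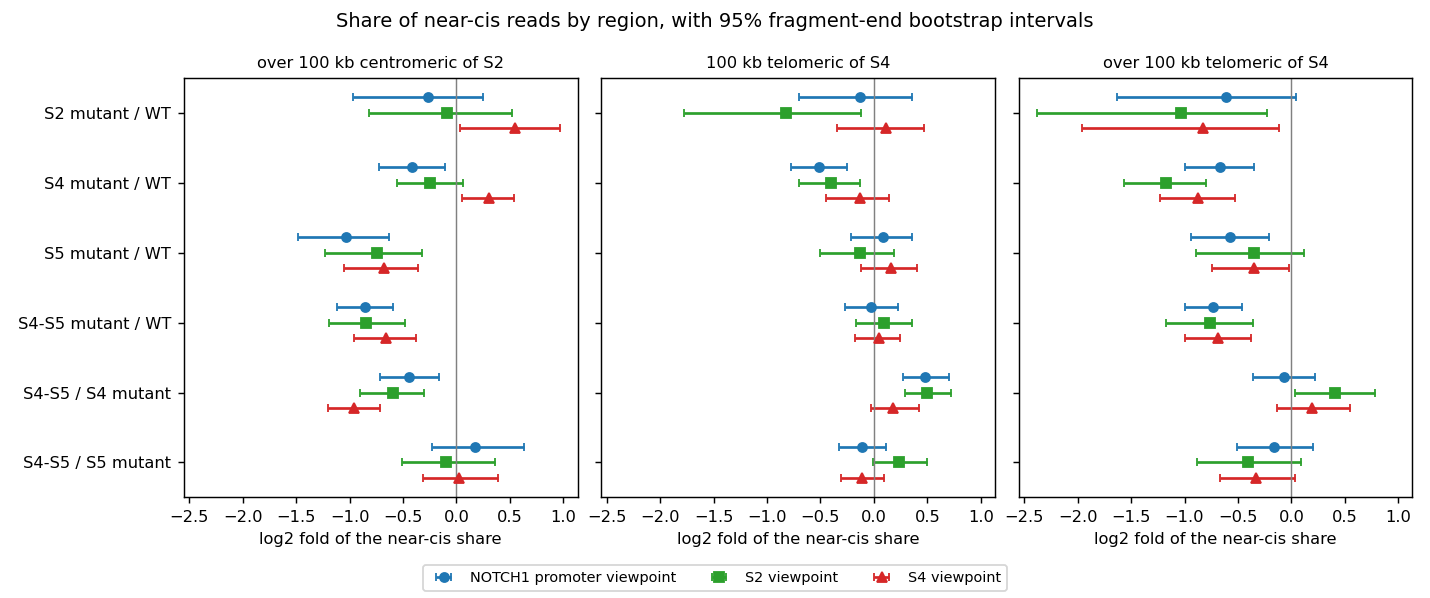
Log2 fold of the share of near-cis reads in 3 regions (horizontal axis), for each mutant against WT and for the S4-S5 mutant against each single mutant; points are folds at the 3 viewpoints and bars are 95% intervals from resampling fragment ends. In the far centromeric region the S4-S5 mutant lies below the S4 mutant at each viewpoint, at -0.44, -0.59 and -0.96.

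Comparing the double mutant with each single mutant, which needs no WT library, the S4-S5 mutant had less far centromeric contact than the S4 mutant from the promoter (log2 -0.44, -0.72 to -0.16), S2 (-0.59, -0.90 to -0.30) and S4 (-0.96, -1.20 to -0.72). Against the S5 mutant the differences were 0.17 (-0.23 to 0.63), -0.10 (-0.51 to 0.36) and 0.02 (-0.32 to 0.38), so that changes of these sizes in either direction were not excluded. The promoter value against the S5 mutant was 0.22 in covered ends, with an interval above 0. That against the S4 mutant was -0.00 in covered ends and -0.26 within 250 kb, with intervals that included 0. In the 100 kb telomeric of S4 the S4-S5 mutant had more contact than the S4 mutant from the promoter (0.48, 0.27 to 0.70) and S2 (0.50, 0.29 to 0.72), and 0.18 (-0.03 to 0.42) from S4, where the interval lay above 0 with a 20-kb mask (0.43), capped ends (0.29) or covered ends (0.09). In covered ends the promoter value there was 0.02 with an interval including 0. From S4, contact with 20 kb around S2 was higher in the S4-S5 mutant than in the S4 mutant (0.28, 0.07 to 0.66) and 0.05 (-0.32 to 0.54) against the S5 mutant. The edgeR test called 86 of 96, 84 of 95 and 85 of 97 bins between the S4-S5 and S4 mutants, and 82, 85 and 86 between the S4-S5 and S5 mutants, at the promoter, S2 and S4. In covered ends it called 0, none of them at an unadjusted p under 0.05. Both region comparisons were added after the data were examined.

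The planned values per library differed among the 5 genotypes in exact permutation tests over every way to part 10 libraries into 5 pairs, in 20 of 21 cases. The 20-kb contact of S4 with S2 was 8.19% ± 0.0516 in WT, 6.66% ± 0.183 in the S2 mutant, 10.5% ± 0.116 in the S4 mutant, 12.4% ± 0.0801 in the S5 mutant and 12.8% ± 0.105 in the S4-S5 mutant (SD, n = 2; exact p = 0.00106, the smallest the test can give, adjusted 0.00165). The contact of S2 with S4 was 9.77% ± 0.0883 in WT and 9.79 to 10.96% in the mutants (exact p = 0.0402, adjusted 0.0412), with bootstrap intervals that included 0 in all 4. With the replicate number as a block, the exact p of this contact no longer lay under 0.05. The interval between S2 and S4 took 58.6% ± 0.109 of near-cis promoter reads in WT and 67.3 to 70.1% in the mutants (exact p = 0.00212, adjusted 0.00269), a gap between WT and all mutants, since against mutant references the log2 folds were -0.03, 0.06, -0.03 and 0.05 with intervals including 0. Seen from S2 it took 44.7% ± 0.000203 against 53.2 to 54.0% (exact p = 0.0667, adjusted 0.0667), the value that did not pass, although its exact p was 0.00317 to 0.0392 with other windows, a wider mask, capped ends or covered ends, and under 0.05 with the replicate number as a block and without S5 replicate 1 or either S4-S5 library. From S4 it took 38.3% ± 0.165 in WT, 31.9% ± 0.123 in the S2 mutant and 44.7% ± 0.600 in the S4-S5 mutant (exact p = 0.00106, adjusted 0.00165). Promoter contacts fell off with distance with a log-log slope of -1.04 ± 0.00246 in WT and -1.23 to -1.29 in the mutants (exact p = 0.00317, adjusted 0.00351). Single pairs of genotypes were not tested on these values, since a permutation of 2 libraries against 2 cannot reach 0.05 and no pooled variance was fitted.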

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

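The tests of a shared template, random pairings, depth, a WT batch, amplified ends, the WT reference, captured ligation events and region interactions were chosen, or had their reading fixed, only after the results were seen.

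The S4 by S5 interaction, which asks whether the S4-S5 mutant departs from the sum of both single effects and so contains the WT libraries, passed the edgeR test in 83 of 96 bins at the promoter, 81 of 95 at S2 and 85 of 97 at S4. On covered ends edgeR called 0 at each, none at an unadjusted p under 0.05, with no other tool run. A gap between WT and all mutants alike enters the interaction with its sign reversed, and so can give such calls by itself. Median log2 folds of bins were negative in every mutant against WT at each viewpoint. For the interaction they were 0.48, 0.39 and 0.37 at the promoter, S2 and S4. The calls and region values here thus do not separate an S4 by S5 interaction from WT standing apart. From the promoter, the region interactions with 95% intervals excluding 0 were log2 -0.20 (-0.31 to -0.10) between S2 and S4, 0.59 (0.06 to 1.14) in the far centromeric region, 0.39 (0.05 to 0.75) in the 100 kb telomeric of S4 (-0.09 on covered ends), 0.50 (0.04 to 0.98) farther telomeric, -0.28 (-0.44 to -0.13) within 50 kb of the viewpoint and -0.32 (-0.59 to -0.05) from S2 to the promoter. From S2 they were -0.26 (-0.44 to -0.06) between S2 and S4 (-0.21 on non-blind ends, interval including 0), 0.64 (0.24 to 1.10) in the 100 kb telomeric of S4 (0.03 on covered and 0.33 on non-blind ends, intervals including 0), 0.77 (0.17 to 1.42) farther telomeric and -0.30 (-0.54 to -0.04) within 50 kb. From S4 only the far telomeric region had one, 0.54 (0.04 to 1.10). Within 250 kb, which keeps only part of each far region, the 3 far telomeric values were 0.02, 1.03 and 0.29 and the far centromeric one 0.36. All of these had intervals that included 0. With a 20-kb mask or on non-blind ends so did the promoter's far centromeric (0.44 and 0.48) and 100 kb telomeric values (0.24 and 0.28; 0.32 within 1 Mb), the far telomeric value from S4 (0.45 and 0.31; 0.39 with capped ends) and, with that mask, the one from the promoter (0.35). Groups of 2 libraries were too small to test for outlying libraries.

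Over 80% of bins changed in each mutant at each viewpoint. The 10 libraries were put into 5 pairs in 100 arrangements, and each of 4 pairs was compared with a reference pair. Only the real arrangement called at least 84 bins at the promoter in all 4 (highest other 46), 80 at S2 (45) and 86 at S4 (48). Other arrangements join unlike libraries, which raises the spread and removes calls. The result thus shows that libraries of 1 genotype resemble each other, and cannot exclude chance sampling of ligation events. Replicates made from 1 ligated template could give as many changed bins without a reproducible genotype effect, and the lowest correlation of a replicate pair lay 0.39 above the highest between genotypes. Log2 ratios of mutant to WT at neighbouring fragment ends correlated at a median of only 0.06 over 12 mutant-viewpoint pairs (0.02 to 0.10), as differences that arise end by end would, although heavy noise at single ends could hide a regional change from this test. The site mutations and other differences between the lines stay open beside sampling of ligation events, and were not tested apart.

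WT libraries had a lower near-cis share and more covered fragment ends than every mutant library. Depth as the cause of the covered ends, but not of the near-cis share, is argued against by libraries thinned to equal near-cis reads, in which WT still covered at least 1.02 times as many ends as the highest mutant library (1.02, 1.42 and 1.31 at the promoter, S2 and S4, the lowest of 20 thinnings). Most mutant libraries, and all at S2, had more near-cis reads than WT and fewer covered ends before thinning, so for them this was hardly a check. It was one for the S2 and S5 mutants at the promoter and the S2 mutant at S4, which had fewer reads than WT. Thinned, these covered 1013 to 1020 ends against a WT mean of 1460, and 1344 and 1350 against 1799. More random ligation in WT remains a candidate explanation, since the WT excess over mutants was at least 2.77 times as large beyond 20 Mb as at 0.5 to 1 Mb (2.77, 5.59 and 4.73). A library batch shared by WT cannot be told apart from genotype, because the smallest gap between the lowest mutant and highest WT near-cis share was 11.6 percentage points and the labels give no batch. An effect common to all 4 mutants is untested for the same reason.

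Both S5-mutated lines had fewer far centromeric contacts at all 3 viewpoints. A few amplified ends as the whole cause are argued against by capped ends, with 6 of 6 folds below 0 with their intervals, and WT standing apart by the mutant references, with 5 of 6. Against those references the S5 mutant had -0.69 (-1.13 to -0.25), -0.58 (-1.08 to -0.10) and -1.11 (-1.45 to -0.76) from the promoter, S2 and S4, and the S4-S5 mutant -0.59 (-1.10 to 0.09, the exception), -0.76 (-1.32 to -0.05) and -1.21 (-1.61 to -0.72). The S2 mutant, low in covered ends, enters both references, so these are not 6 separate checks. From S4 the reference lines lay above WT (15.7% in the S2 mutant and 13.2% in the S4 mutant against 10.7%), which enlarges the folds there. Fewer captured ligation events in the S5-mutated lines cannot be told apart, since the far centromeric share of covered ends was lowered more than the telomeric in 3 of 6 cases, and covered ends had folds of only -0.35 to -0.06. Thinned to equal near-cis reads, the S5 mutant covered the fewest ends at S2 (1039 and 1068). At S4 the S5 mutant (1154 and 1165) and the S4-S5 mutant (1184 and 1194) covered the fewest. At the promoter the S5 mutant was near the lowest (1017 and 1020), but the S4-S5 mutant covered the most of the mutants (1392 and 1395). Covered ends ignore read numbers, and on them the S5 mutant's interval from S4 included 0, so uneven amplification stays open too. From the promoter and S2, the S2 mutant fell farther on covered ends than either S5-mutated line. Covered ends were not matched for depth, and among the mutants the S2 mutant had the fewest near-cis reads at both. Loss of S5 may lower far centromeric contacts, a hypothesis found and tested on the same data in lines whose replicates may share a template.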

How the results depend on the processing

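The tests with mutant references, summed replicates, a minimum of 2-fold, non-blind ends, spill-over removal, no S2 mutant, chromosome 9 scaling of region folds and the count of replicate directions were chosen only after the results were seen. The percent of bins changed stayed within 1.5 times its reported value, at 72.6 to 100%, under every alternative except covered ends, the summed additive model and a 2-fold minimum. On covered ends the edgeR test called 0% of bins in all 24 cases, with 58, 63 and 63 bins tested at the promoter, S2 and S4. At an unadjusted p under 0.05 it called 8 bins in the S2 mutant, 1 in the S5 mutant and 1 among genotypes at the promoter, 1 in the S4 mutant at S2 and 0 elsewhere, and no other tool was run on them. Power on covered ends was not simulated, so these 0 calls do not show that bins were unchanged. The additive edgeR model on summed replicates also called 0% in 12 cases, with 20, 3, 5 and 2 bins unadjusted in the S2, S4, S5 and S4-S5 mutants at the promoter, 30, 2, 4 and 4 at S2 and 25, 4, 5 and 4 at S4 (no other tool was run). In simulations that model recovered 0 of 10 bins changed 2-fold at each viewpoint and 1, 0 and 2 of 10 changed 4-fold, so its 0 calls do not show that bins were unchanged. A 2-fold minimum left 56.2, 30.2, 43.8, 30.2, 19.8, 29.2 and 45.8% of promoter bins in the S2, S4, S5 and S4-S5 mutants, the S4-S5 mutant against the S4 and S5 mutants, and the interaction, by construction. The same values were 65.3, 36.8, 40, 29.5, 32.6, 41.1 and 49.5% at S2 and 59.8, 29.9, 30.9, 38.1, 30.9, 26.8 and 42.3% at S4.

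The exact p for the S2-to-S4 interval seen from S2 (0.0667) was 0.0138 on covered ends, 0.00317 with a 20-kb mask, 0.0392 within 250 kb, 0.00741 within 1 Mb, 0.0127 with capped ends and 0.036 to 0.0974 without 1 library in turn, under 0.05 without S5 replicate 1 or either S4-S5 library. On covered ends the exact p of contact with the promoter was 0.186 from S2 (0.00423 with reads) and 0.122 from S4 (0.00212). With the replicate number as a replicate block, the exact p was 0.0417 for the S2-to-S4 interval from S2 and 0.075 for the contact of S2 with S4, and 82.1 to 100% of bins changed. The replicate number was not read as a pairing, since deviations between the replicates correlated at medians of 0.04, 0.07 and 0.10 over 10 genotype pairs per viewpoint (-0.34 to 0.48 in all), not above 0 in every pair. Yet at S2 replicate 2 lay above replicate 1, or below it, in all 5 genotypes for 6 of 14 values per library, against 0.875 if the numbers were unrelated and the values independent, which they are not, and for 2 of 14 at S4 and 0 of 14 at the promoter. Something shared by libraries of 1 number at S2 is therefore not excluded, and both calls that the block changed belong to that viewpoint.

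Log2 folds that turned, or that gained or lost a 95% interval excluding 0, follow with the reported value in brackets, and for bins those that turned. Near-cis scaling centres each library on its own total, and other scalings moved the median log2 fold change of bins by 0.23 to 0.36 (chromosome 9), 0.24 to 0.69 (TMM) and 0.27 to 1.12 (DESeq2), which accounts for turns of bins with smaller changes. The cause was not tested for the other settings. By DESeq2, bins seen from the promoter had 0.21 (-0.87) from 139510001 and 0.68 (-0.40) from 139490001 in the S2 mutant, 0.54 (-0.08) from 139380001, 0.44 (-0.18) from 139510001 and 0.08 (-0.53) from 139490001 in the S4 mutant, 0.11 (-0.61) from 139490001 in the S5 mutant, and 0.12 (-0.56) from 139490001 in the S4-S5 mutant. By DESeq2, bins seen from S2 had 0.17 (-0.21) from 139520001 in the S4 mutant, 0.24 (-0.16) from 139520001 and 0.15 (-0.24) from 139530001 in the S5 mutant, and 0.31 (-0.11) from 139520001 in the S4-S5 mutant. By DESeq2, bins seen from S4 had 0.52 (-0.35) from 139380001 and 0.66 (-0.21) from 139400001 in the S2 mutant. With TMM factors, bins seen from the promoter had 0.25 (-0.40) from 139490001 in the S2 mutant, and 0.24 (-0.08) from 139380001 and 0.14 (-0.18) from 139510001 in the S4 mutant. With TMM factors, bins seen from S2 had 0.10 (-0.21) from 139520001 in the S4 mutant, 0.20 (-0.16) from 139520001 and 0.12 (-0.24) from 139530001 in the S5 mutant, and 0.24 (-0.11) from 139520001 in the S4-S5 mutant. With TMM factors, bins seen from S4 had 0.23 (-0.35) from 139380001 and 0.37 (-0.21) from 139400001 in the S2 mutant. From the promoter with chromosome 9 scaling, the far centromeric region had -0.10 (-0.42) in the S4 mutant, the 100 kb telomeric of S4 had -0.19 (-0.51) in the S4 mutant, 0.45 (0.09) in the S5 mutant and 0.28 (-0.03) in the S4-S5 mutant, and the far telomeric region had -0.21 (-0.57) in the S5 mutant. From S2 with chromosome 9 scaling, the far centromeric region had -0.41 (-0.74) in the S5 mutant, the 100 kb telomeric of S4 had -0.60 (-0.82) in the S2 mutant, -0.08 (-0.40) in the S4 mutant and 0.40 (0.10) in the S4-S5 mutant, and the far telomeric region had -0.81 (-1.04) in the S2 mutant. From S4 with chromosome 9 scaling, the 100 kb telomeric of S4 had 0.45 (0.16) in the S5 mutant and 0.31 (0.05) in the S4-S5 mutant, and the far telomeric region had -0.57 (-0.83) in the S2 mutant and -0.06 (-0.35) in the S5 mutant. With chromosome 9 scaling, bins seen from the promoter had 0.23 (-0.08) from 139380001 and 0.14 (-0.18) from 139510001 in the S4 mutant. With chromosome 9 scaling, bins seen from S2 had 0.11 (-0.21) from 139520001 in the S4 mutant, 0.17 (-0.16) from 139520001 in the S5 mutant, and 0.20 (-0.11) from 139520001 in the S4-S5 mutant.

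From the promoter against mutant references, the interval from S2 to S4 had -0.03 (0.21) in the S2 mutant, 0.06 (0.26) in the S4 mutant, -0.03 (0.20) in the S5 mutant and 0.05 (0.26) in the S4-S5 mutant, the contact with S4 had 0.58 (0.36) in the S4-S5 mutant, the far centromeric region had 0.23 (-0.42) in the S4 mutant and -0.59 (-0.86) in the S4-S5 mutant, the 100 kb telomeric of S4 had 0.40 (0.09) in the S5 mutant, and the far telomeric region had -0.07 (-0.67) in the S4 mutant, 0.06 (-0.57) in the S5 mutant and -0.12 (-0.74) in the S4-S5 mutant. From S2 against mutant references, the interval from S2 to S4 had -0.01 (0.25) in the S4 mutant, 0.02 (0.27) in the S5 mutant and 0.00 (0.26) in the S4-S5 mutant, the 100 kb telomeric of S4 had 0.08 (-0.40) in the S4 mutant, 0.48 (-0.13) in the S5 mutant and 0.92 (0.10) in the S4-S5 mutant, and the far telomeric region had -0.27 (-1.04) in the S2 mutant, -0.48 (-1.18) in the S4 mutant and 0.27 (-0.76) in the S4-S5 mutant. From S4 against mutant references, the 100 kb telomeric of S4 had -0.27 (-0.13) in the S4 mutant, and the far telomeric region had -0.19 (-0.83) in the S2 mutant, -0.29 (-0.88) in the S4 mutant, 0.50 (-0.35) in the S5 mutant and 0.14 (-0.69) in the S4-S5 mutant. Against mutant references, bins seen from the promoter had -0.36 (0.11) from 139520001 and 0.16 (-0.40) from 139490001 in the S2 mutant, 0.23 (-0.18) from 139510001 and -0.50 (0.11) from 139500001 in the S4 mutant, and -0.05 (0.71) from 139500001, 2.74 (-2.93) from 139070001, 3.17 (-2.46) from 139790001 and -0.15 (0.23) from 139380001 in the S4-S5 mutant. Against mutant references, bins seen from S2 had -0.17 (0.12) from 139510001 in the S2 mutant, -0.91 (1.43) from 138960001 in the S4 mutant, and 3.30 (-4.42) from 139770001, 4.07 (-3.16) from 139210001 and -0.17 (0.13) from 139440001 in the S4-S5 mutant. Against mutant references, bins seen from S4 had -0.96 (1.64) from 139020001 in the S4 mutant, -0.57 (1.90) from 139020001 in the S5 mutant, and -0.42 (0.95) from 139960001 and -0.80 (0.09) from 139440001 in the S4-S5 mutant.

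From the promoter on covered ends, the contact with S4 had 0.08 (0.36) in the S4-S5 mutant, the far centromeric region had -0.38 (-0.27) in the S2 mutant, -0.00 (-0.44) in the S4-S5 mutant against the S4 mutant and 0.22 (0.17) in the S4-S5 mutant against the S5 mutant, the 100 kb telomeric of S4 had -0.00 (-0.51) in the S4 mutant, 0.11 (0.09) in the S5 mutant, 0.02 (0.48) in the S4-S5 mutant against the S4 mutant, -0.09 (-0.12) in the S4-S5 mutant against the S5 mutant and -0.09 (0.39) in the S4 by S5 interaction, and the far telomeric region had -0.09 (-0.67) in the S4 mutant and 0.01 (-0.74) in the S4-S5 mutant. From S2 on covered ends, the far centromeric region had -0.17 (-0.09) in the S2 mutant, and the 100 kb telomeric of S4 had 0.09 (-0.82) in the S2 mutant, -0.01 (-0.40) in the S4 mutant, 0.09 (0.10) in the S4-S5 mutant and 0.03 (0.64) in the S4 by S5 interaction. From S4 on covered ends, the far centromeric region had -0.02 (0.55) in the S2 mutant, 0.02 (0.30) in the S4 mutant and -0.06 (-0.68) in the S5 mutant, and the 100 kb telomeric of S4 had 0.15 (0.11) in the S2 mutant, 0.17 (0.16) in the S5 mutant, 0.14 (0.05) in the S4-S5 mutant and 0.09 (0.18) in the S4-S5 mutant against the S4 mutant.

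From the promoter with a 20-kb mask, the interval from S2 to S4 had 0.22 (0.21) in the S2 mutant, the far centromeric region had -0.21 (-0.42) in the S4 mutant and 0.44 (0.59) in the S4 by S5 interaction, the 100 kb telomeric of S4 had 0.24 (0.39) in the S4 by S5 interaction, and the far telomeric region had 0.35 (0.50) in the S4 by S5 interaction. From S2 with a 20-kb mask, the 100 kb telomeric of S4 had -0.61 (-0.82) in the S2 mutant, 0.24 (0.10) in the S4-S5 mutant and 0.34 (0.23) in the S4-S5 mutant against the S5 mutant. From S4 with a 20-kb mask, the 100 kb telomeric of S4 had -0.35 (-0.13) in the S4 mutant and 0.43 (0.18) in the S4-S5 mutant against the S4 mutant, and the far telomeric region had -0.71 (-0.83) in the S2 mutant, -0.28 (-0.35) in the S5 mutant and 0.45 (0.54) in the S4 by S5 interaction. With a 20-kb mask, bins seen from the promoter had 0.13 (-0.08) from 139380001 in the S4 mutant. From the promoter within 250 kb, the contact with S2 had 0.46 (0.56) in the S5 mutant, the contact with S4 had 0.26 (0.36) in the S4-S5 mutant, the far centromeric region had -0.34 (-0.42) in the S4 mutant, -0.62 (-1.03) in the S5 mutant, -0.26 (-0.44) in the S4-S5 mutant against the S4 mutant and 0.36 (0.59) in the S4 by S5 interaction, and the far telomeric region had -0.43 (-0.67) in the S4 mutant, -0.23 (-0.57) in the S5 mutant and 0.02 (0.50) in the S4 by S5 interaction. From S2 within 250 kb, the far centromeric region had -0.52 (-0.25) in the S4 mutant, and the far telomeric region had -0.37 (-1.04) in the S2 mutant, -0.54 (-0.76) in the S4-S5 mutant and 1.03 (0.77) in the S4 by S5 interaction. From S4 within 250 kb, the interval from S2 to S4 had 0.13 (0.22) in the S4-S5 mutant, the far centromeric region had -0.06 (0.55) in the S2 mutant and 0.13 (0.30) in the S4 mutant, and the far telomeric region had -0.52 (-0.83) in the S2 mutant, -0.27 (-0.35) in the S5 mutant and 0.29 (0.54) in the S4 by S5 interaction. Within 250 kb, bins seen from the promoter had -0.06 (0.04) from 139510001 in the S5 mutant. The far regions within 250 kb are only the parts nearest the viewpoint, and within 1 Mb they are longer. From the promoter within 1 Mb, the 100 kb telomeric of S4 had 0.32 (0.39) in the S4 by S5 interaction. From S2 within 1 Mb, the far centromeric region had -0.31 (-0.25) in the S4 mutant, and the far telomeric region had -0.49 (-1.04) in the S2 mutant. From S4 within 1 Mb, the far centromeric region had 0.36 (0.55) in the S2 mutant and 0.14 (0.30) in the S4 mutant. Within 1 Mb, bins seen from S4 had 2.00 (-8.01) from 140020001 in the S2 mutant. From S2 with capped ends, the 100 kb telomeric of S4 had 0.30 (0.23) in the S4-S5 mutant against the S5 mutant. From S4 with capped ends, the far telomeric region had -0.26 (-0.35) in the S5 mutant and 0.39 (0.54) in the S4 by S5 interaction, and the 100 kb telomeric of S4 had 0.29 (0.18) in the S4-S5 mutant against the S4 mutant. From the promoter on non-blind ends, the contact with S4 had 0.30 (0.36) in the S4-S5 mutant, the far centromeric region had 0.48 (0.59) in the S4 by S5 interaction, and the 100 kb telomeric of S4 had 0.28 (0.39) in the S4 by S5 interaction. From S2 on non-blind ends, the interval from S2 to S4 had 0.19 (0.27) in the S5 mutant and -0.21 (-0.26) in the S4 by S5 interaction, and the 100 kb telomeric of S4 had -0.54 (-0.82) in the S2 mutant, -0.18 (-0.40) in the S4 mutant, 0.39 (0.10) in the S4-S5 mutant and 0.33 (0.64) in the S4 by S5 interaction. From S4 on non-blind ends, the interval from S2 to S4 had 0.16 (0.22) in the S4-S5 mutant, the far centromeric region had 0.43 (0.55) in the S2 mutant and 0.31 (0.30) in the S4 mutant, the 100 kb telomeric of S4 had 0.48 (0.16) in the S5 mutant and -0.26 (-0.11) in the S4-S5 mutant against the S5 mutant, and the far telomeric region had -0.83 (-0.83) in the S2 mutant, -0.35 (-0.35) in the S5 mutant and 0.31 (0.54) in the S4 by S5 interaction. On non-blind ends, bins seen from the promoter had -4.14 (1.87) from 139710001 in the S2 mutant, 0.05 (-0.08) from 139380001 in the S4 mutant, and -0.05 (0.04) from 139510001 in the S5 mutant. On non-blind ends, bins seen from S2 had 0.61 (-0.35) from 139530001 in the S4 mutant, 0.27 (-0.16) from 139520001 and 0.63 (-0.24) from 139530001 in the S5 mutant, and 0.21 (-0.11) from 139520001 in the S4-S5 mutant. On non-blind ends, bins seen from S4 had -0.17 (0.13) from 139360001 in the S4 mutant, and -0.28 (0.18) from 139360001 in the S4-S5 mutant. From the promoter over 10-kb contact windows, the contact with S2 had 0.68 (0.56) in the S5 mutant, and the contact with S4 had 0.32 (0.36) in the S4-S5 mutant. From the promoter over 40-kb contact windows, the contact with S2 had 0.28 (0.56) in the S5 mutant. Leaving out 1 library in turn, the fold of the S4-S5 against the S5 mutant in the 100 kb telomeric of S4 seen from S2 ran from 0.22 to 0.25, and its interval excluded 0 without S5 replicate 1 or S4-S5 replicate 2.

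Folds of 4 intervals nearer to the viewpoints were left out after their alternatives had been seen, in part for length. Of their 23 folds of a mutant against WT with intervals excluding 0, 11 reversed and 6 weakened against mutant references, 3 reversed and 1 weakened on covered ends, and 1 reversed and 13 weakened on non-blind ends. A further 8 weakened with a 20-kb mask, 7 within 250 kb, 3 with chromosome 9 scaling and 2 with capped ends. Signal on other chromosomes, genome-wide scaling, pseudocounts and counts per gene were planned but not run, because the tables hold counts on chromosome 9 only and no hg19 annotation was used here. Of the named bin values, 64 no longer passed on covered ends, 116 in the summed additive model, 15 against mutant references and 9 on non-blind ends without turning, and leaving out 1 library ended 1 to 3 of these calls or none. Calls were also lost within 250 kb (5), with capped ends (4), within 1 Mb (3), with chromosome 9 scaling (3) and with a 20-kb mask (2). DESeq2, TMM factors and only the 4 libraries compared each ended 1. Removing spill-over changed no region fold or bin call. At the promoter the S2 mutant had the fewest near-cis reads. At every viewpoint it had the lowest mean share of near-cis ends with a read, 34.1, 39.4 and 41.3% at the promoter, S2 and S4. Its covered near-cis ends held medians of 3 to 5 reads, against 59 to 228 in WT. Its counts of bins changed at least 2-fold, the highest at each viewpoint, were not separated from this.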

Other observations

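The test of reciprocal contact was chosen, and its reading settled, only after the results were seen.

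WT reads were spread farther along chromosome 9 than those of any mutant. From the promoter, 8.23% ± 0.0382 of WT reads outside the mask lay beyond 20 Mb (SD, n = 2), against 1.65% ± 0.0259 in the S2 mutant, 1.68% ± 0.00242 in the S4 mutant, 2.52% ± 0.0549 in the S5 mutant and 2.16% ± 0.0448 in the S4-S5 mutant. From S2 the WT share was 8.29% ± 0.0342 and the mutants had 0.976 to 1.88%, and from S4 6.39% ± 0.0332 and 0.663 to 1.39%. Nearest to the viewpoint, up to 50 kb, the order was the opposite, with 29.9% ± 0.0537 of WT promoter reads against 43.4 to 47.1% in the mutants. The S5 mutant had the highest share beyond 20 Mb among the mutants at each viewpoint, and the WT share differed from that of every mutant by more than the SDs.

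The contact between S2 and S4 was measured from both ends. If it changed alike, log2 folds of the 20-kb contact window would agree between viewpoints, and the difference between them had an interval that excluded 0 in 0 of 4 mutants. The fold seen from S4 minus that from S2 was -0.30 (-1.25 to 0.69) in the S2 mutant, 0.34 (-0.34 to 0.95) in the S4 mutant, 0.44 (-0.37 to 1.19) in the S5 mutant and 0.48 (-0.00 to 0.99) in the S4-S5 mutant. Intervals this wide cannot tell whether the S2 and S4 contact changed alike from both ends.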
